A study of Mus musculus with 10 samples.

How the data were processed

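Gene expression was measured on Affymetrix microarrays, which read biotin-labelled RNA with short DNA probes, in total RNA of bEnd3 cells, a line of mouse brain endothelial cells immortalised with the polyoma middle T antigen. The cells had been transduced with a lentivirus and selected with puromycin. In 5 samples the virus carried mouse Gata4 ahead of mCherry and a puromycin resistance gene, and in 5 samples it carried mCherry and the resistance gene alone (empty vector). Sample titles call the 5 samples of each group biological replicates. They do not say whether each sample came from a transduction of its own, so the p-values measure the spread between these samples and may miss the spread between transductions.

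The deposited table holds log2 expression values that the authors made with RMA (background correction, quantile normalization and summary of the probes of a feature), per the submitters' processing notes. The RMA version, the probe annotation and the genome build are not given in the sources used here, so no genome coordinates are printed. All 10 columns had the same quartiles up to rounding, with a median of 4.16 and a range of 2.37 to 13.9 on the log2 scale. The table holds 23748 features with 1 value per sample. Quantile normalization forces the arrays to share 1 distribution of values. A shift of all genes in 1 direction would therefore be hidden, and every change below is relative to the other genes. The table carries no detection call. Values near the lower end may be background, and a fold against a group near that end can be understated. For arrays the number of arrays, here 5 per group, limits the precision.

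Gene symbols came from the platform annotation, which pairs each feature with an Entrez gene. Of the features, 23111 had 1 symbol, 0 had several and 637 had none. The 23111 named features each stood for a different gene, so no rule for choosing between features was needed, and 23081 of their symbols were also in a RefSeq gene table (GRCm38.p6). Of the 466 genes in the preset lists, 444 were measured under a named feature.

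Group means were compared with limma (version 3.58.1, R 4.3.3; lmFit and eBayes without a trend) over all 10 samples and 23111 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of single genes come from this fit unless another test is named, and an error written as SE is the moderated standard error of the log2 change. Group levels are means ± SD over 5 samples. A total of 29 gene lists was written before the data were examined, as were the comparison, the alternatives and the rule for naming genes. The lists comprised 5 on the question in the series title, 19 on pathways of endothelial cells or of the viral and drug treatment, and 5 on markers of other cell types. Lists were tested with camera at a preset inter-gene correlation of 0.01, as a two-sided test adjusted over the 29 lists. Camera asks whether a list moved against all other genes. The same test with a correlation estimated from the data, and fry, stood beside it. With an estimated correlation, 0 of the 29 lists passed (4 at an unadjusted p under 0.05), against 8 with the preset one. Fry, which asks whether the genes of a list moved on balance in 1 direction, called 24 lists. It does not compare a list with the other genes. With 25.6% of all genes called, many fry calls were to be expected.

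Named genes followed this rule: all GATA factors and their FOG cofactors; the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, leaving out gene models and clone names (0 were left out); for each of the 5 lists on the series question up to 3 called genes in each direction, and for each other list up to 2. This gave 118 genes. Any gene named outside the rule is marked as such.

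The fit was tested on simulated data with the real means and spreads of the 23111 genes of this comparison, in which 200 genes were changed. It recovered 78.8% of the genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2. False calls made up 2.63% of all calls. A shift of the cell cycle list by -0.4 was found among 29 lists, and 0 lists sharing no gene with it were called. The simulated genes varied independently of each other, and far fewer were changed than the 5915 called in the data. The simulation therefore does not test the list calls under correlation between genes, on which they depended.

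Replicates were compared before averaging. Correlations between arrays of a group lay between 0.9964 and 0.9977 and those between groups between 0.9842 and 0.9864, and 0 pairs of columns were identical. The first principal component held 73.5% of the variance. On the second (5.27%), empty-vector samples 1 and 2 (-13.0 and -14.6) lay apart from empty-vector samples 3 to 5 (5.74 to 13.5). The Gata4 samples lay between -5.21 and 5.02. The cause of this split of the empty-vector samples was not tested. The groups share replicate numbers 1 to 5. The numbers were not treated as pairs. The alternatives were the replicate number as a block, an intensity trend, a robust trend, array weights, centring on array medians, a further quantile normalization, filters on dim genes, a test of every feature, an exact rank-sum test, a test against a 1.5-fold change, the other set tests, and each sample left out in turn.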

Results

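The expression of 23111 genes was measured in 10 samples of the mouse brain endothelial cell line bEnd3, 5 transduced with Gata4 and 5 with the empty vector. GATA4 is a zinc finger transcription factor of heart, gut and liver endothelium. According to its title, the study asked how GATA4 acts in organ-specific endothelial differentiation, in liver development and in the formation of blood cells in the embryo. The comparison of the groups therefore asks which genes change when GATA4 is placed in endothelial cells of a continuous vessel bed. Levels are RMA values on the log2 scale, given as mean ± SD over 5 samples.

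The Gata4 feature stood at 5.08 ± 0.17 in the Gata4 samples and at 4.75 ± 0.16 in the empty-vector samples, a difference of 0.34 ± 0.09 (SE), or 1.26-fold with a 95% interval of 1.10 to 1.45. It passed the threshold (limma, adjusted p = 0.017), and an exact two-sided permutation test over the 252 assignments of the samples gave p = 0.024, where 0.0079 is the smallest possible. The groups overlapped: 1 Gata4 sample at 4.83 lay below the highest empty-vector sample at 4.93. The vector carried a codon-optimized cDNA, whose sequence differs from that of the mouse gene, so this feature need not detect the transgene. Among the relatives of Gata4, Gata3 rose by 0.65 ± 0.07 (SE) and Gata2, a GATA factor of most endothelium, fell by 0.31 ± 0.06 (SE). Zfpm1, which encodes the GATA cofactor FOG1, rose 2.79-fold, from 6.91 ± 0.08 to 8.39 ± 0.11 (adjusted p = 2.9e-09). Gata1, Gata5, Gata6 and Zfpm2 did not pass the test, with log2 changes of -0.11, -0.01, -0.22 and -0.12. Of the 8 genes of this list, 3 were higher and 1 was lower, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.58), whose median was -0.06 against a mean of 0.21 and an upward camera direction.

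**Figure D1:**
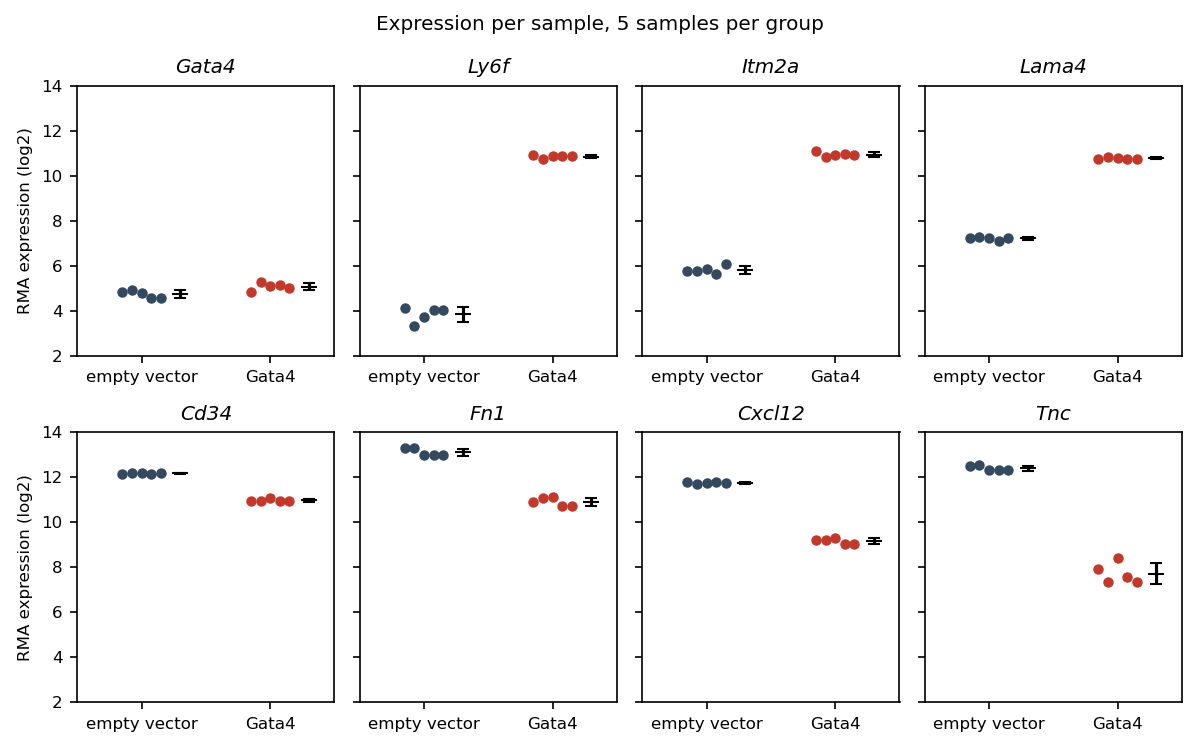
RMA expression (log2, vertical axis) of 8 genes in each of the 5 empty-vector and 5 Gata4 samples (points), with the group mean and SD (black bars). The groups of Gata4 overlapped, whereas those of Ly6f (3.86 against 10.87) and Cxcl12 (11.77 against 9.18) lay far apart.

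The transcriptomes of the groups differed widely. At an adjusted p under 0.05, 2857 genes were higher and 3058 lower in the Gata4 samples, together 25.6% of the genes tested. Most changes were small: 4207 of the 5915 called genes changed by at most 1.5-fold, while 406 were at least 2-fold higher and 324 at least 2-fold lower. The values of the 2 groups did not overlap for 4865 genes (21.1%), against 0.79% expected by chance. The largest measured rise was that of Ly6f, a member of the Ly6 family of membrane-anchored proteins, from 3.86 ± 0.33 to 10.87 ± 0.06, or 128-fold. Tmem255a rose 114-fold, the secreted leucine-rich protein gene Nepn 66.2-fold and the serine protease inhibitor gene Serpinb1a 51.8-fold. The ATP-gated channel gene P2rx2 rose 44.5-fold, Mctp1 44.1-fold, Itm2a 34.9-fold and Nts, which encodes the peptide neurotensin, 32.2-fold. In the empty-vector samples 5 of these 8 genes had low means, from 3.45 for Mctp1 to 4.29 for Serpinb1a, where the median of all features was 4.16. The largest measured fall was that of the cytokine gene Il24, from 8.38 ± 0.25 to 3.49 ± 0.30, or 29.7-fold. Tnc, which encodes the matrix protein tenascin C, was 25.5-fold lower, the sialyltransferase gene St8sia6 25.2-fold and the phosphodiesterase gene Pde1a 24.5-fold. Tc2n, Ramp3 (a partner of the adrenomedullin receptor), Tmem252 and the adenylate kinase gene Ak5 were 17.7-, 16.8-, 16.1- and 13.7-fold lower. In the Gata4 samples Il24, Pde1a, St8sia6 and Ak5 had low means of 3.49, 3.65, 3.78 and 4.10, whereas Tnc stood at 7.73 ± 0.46. Folds against such low means can be understated, so the order of the rises and of the falls is that of the measured values. The groups did not overlap for any of these genes, and the highest adjusted p among them was that of Tc2n (3.1e-09).

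Genes of liver sinusoidal endothelium, the fenestrated endothelium of the liver, changed in both directions. Of 25 such genes, 9 were higher, 5 lower and 11 did not pass the test, with the same counts when adjusted over the list alone. The list's median change was 0.11 and camera did not call it (adjusted p = 0.23). Of the 25 genes 11 had a mean level below the median of all genes, a range in which few genes were called. The largest rises were those of Plxnc1, a semaphorin receptor gene (2.07 ± 0.08 SE), the interleukin gene Il1a (1.51 ± 0.26 SE) and Gpr182, an endothelial receptor gene that rose from 4.64 ± 0.17 to 6.07 ± 0.21. The scavenger receptor gene Stab1 rose by 0.54 ± 0.08 (SE). The largest falls were those of the Wnt enhancer gene Rspo3 (6.59-fold), the coagulation factor gene F8 (2.77-fold) and Stab2, a hyaluronan scavenger receptor gene (2.68-fold). Plxnc1 and Il1a had low means in the empty-vector samples (3.44 and 3.14), and Stab2 in the Gata4 samples (3.71), where values may be background. In the Gata4 samples Il1a stood at 4.65 ± 0.68. Lyve1, Fcgr2b and Kdr were chosen after their values were seen. Lyve1 and Fcgr2b, markers of sinusoidal endothelium, had log2 changes of 0.15 and -0.01 that did not pass the test (adjusted p = 0.26 and 0.95), and the VEGF receptor gene Kdr fell by 1.18.

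Genes of continuous endothelium fell more often than they rose. Of 23 measured, 11 were lower, 6 higher and 6 did not pass; adjusted over the list alone, 12 were lower and 7 higher. The median change was -0.16 but the mean was -0.01, and camera did not call the list (adjusted p = 0.12). Cd34, a sialomucin of capillary endothelium, fell from 12.19 ± 0.02 to 10.99 ± 0.06, or 2.29-fold. Mcam, an adhesion molecule gene, was 3.00-fold lower and Esm1, a marker of sprouting endothelium, 3.25-fold lower. The opposite direction was taken by Ly6c1 (5.64-fold higher), the von Willebrand factor gene Vwf (3.68-fold higher) and the tetraspanin gene Cd9 (3.37-fold higher). Cdh5, the VE-cadherin gene, and Pecam1 were chosen after their values were seen. Cdh5 fell by 0.25 (adjusted p = 0.0022), and Pecam1 had a log2 change of -0.12 that did not pass the test (adjusted p = 0.090). When genes standing in several lists were left out, camera called the sinusoidal list higher (adjusted p = 0.020) and the continuous list lower (adjusted p = 0.027). Among the genes left out of the sinusoidal list were Rspo3, Stab2, Kdr and Flt4, which fell, and Stab1, which rose. Its largest rises, Plxnc1, Il1a and Gpr182, stayed. The continuous list lost, among others, Vwf, which rose, and Cldn5, which fell. The gained calls thus depend on which genes were dropped. With an estimated correlation neither list was called (adjusted p = 0.59 for both). Over all alternative camera settings the adjusted p ranged from 0.020 to 0.67 for the sinusoidal list and from 0.027 to 0.59 for the continuous one.

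Genes of the brain endothelial barrier and of the basement membrane also split. Of 23 barrier genes, 4 were higher and 7 lower, with the same counts adjusted over the list alone, and 12 did not pass. Camera did not call the list (adjusted p = 0.82), whose median change (0.02) was positive while its mean (-0.01) and camera's direction were negative. Ocln, which encodes the tight junction protein occludin, rose 8.05-fold, from 6.78 ± 0.36 to 9.78 ± 0.04, while Cldn5, which encodes claudin 5 of the same junctions, was 2.06-fold lower. Abcg2, an efflux transporter gene, was 3.00-fold lower and the transferrin receptor gene Tfrc 1.91-fold lower. Spock2 and the amino acid transporter gene Slc7a5 rose by 0.37 and 0.32. Of 18 basement membrane genes, 6 were higher and 7 lower, again with the same counts over the list alone (camera, adjusted p = 0.80). The laminin genes Lama4 and Lamb1 rose 11.9-fold and 2.44-fold and Agrn, which encodes agrin, 1.63-fold. Fn1, the fibronectin gene, was 4.60-fold lower, Col18a1 3.54-fold and Lama5 1.48-fold. The mean of the basement membrane list was 0.05 and fry called it higher (adjusted p = 0.0097), whereas its median was -0.04 and camera's direction was lower.

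**Figure D2:**
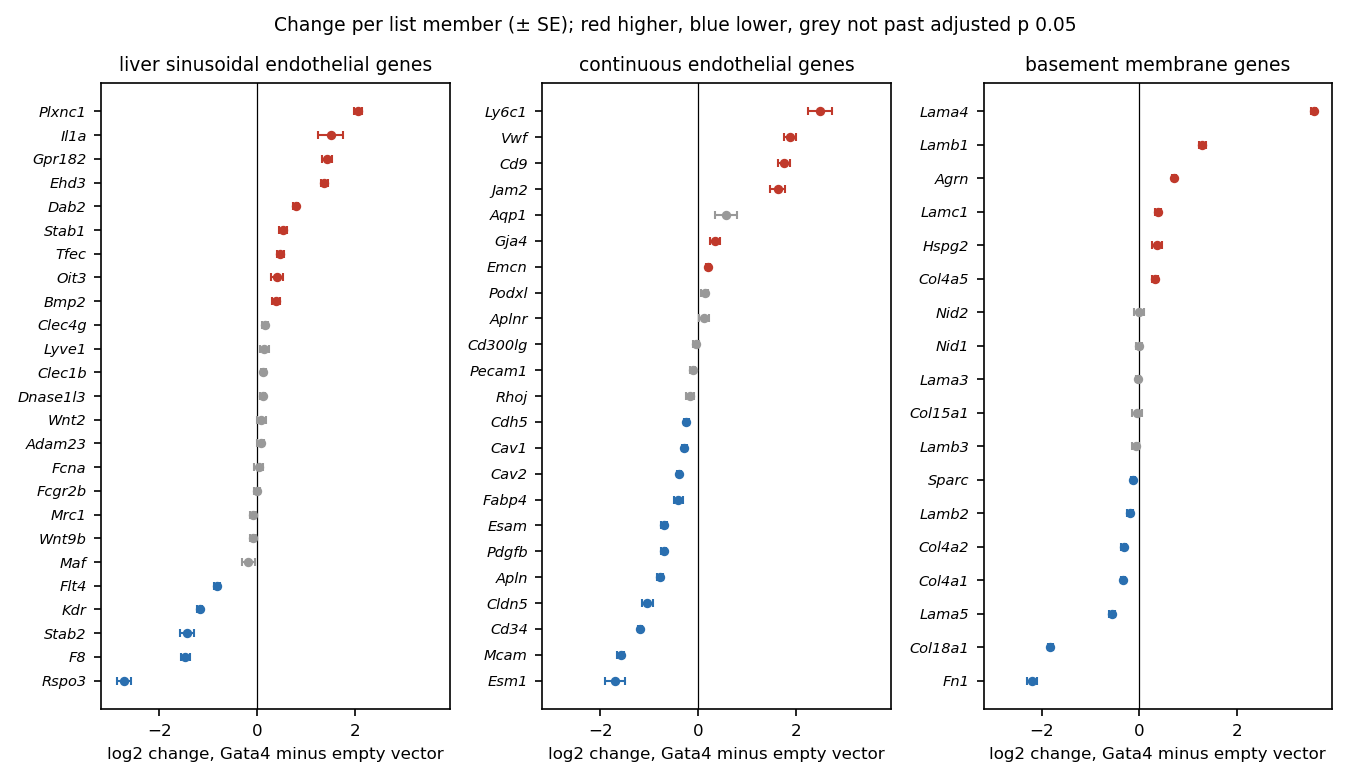
Log2 change from empty-vector to Gata4 samples (horizontal axis, points with SE) for each measured gene of 3 lists, coloured by whether it was higher, lower or not past an adjusted p of 0.05. In each list genes lay on both sides of 0, from Plxnc1 (2.07) to Rspo3 (-2.72) among sinusoidal genes.

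Angiocrine factors, signals that endothelial cells send to their organ, changed in both directions. Of 24 genes, 9 were higher and 9 lower (11 and 9 adjusted over the list alone), and camera did not call the list (adjusted p = 0.74). Its median (0.03) was positive, and its mean (-0.09) and camera's direction were negative. Igf1, the insulin-like growth factor gene, rose 13.3-fold, from 5.10 ± 0.49 to 8.84 ± 0.10. Hgf, which encodes the hepatocyte growth factor, rose 3.46-fold and Angpt2, a ligand gene of the TIE2 receptor, 1.99-fold. Rspo3 fell 6.59-fold, the chemokine gene Cxcl12 fell 6.04-fold from 11.77 ± 0.04 to 9.18 ± 0.12, and Bmp4 was 3.12-fold lower.

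Among 23 endothelial transcription factors, 9 were higher and 6 lower (10 and 6 adjusted over the list alone). Camera did not call this list (adjusted p = 0.69), with a median of 0.03 and an upward direction against a mean of -0.02. Sox18 was 4.73-fold lower and Epas1, the hypoxia-inducible factor HIF2 alpha gene, 2.13-fold lower, whereas Sox17 rose 2.50-fold and Ets2 1.84-fold. Of 12 arterial genes 6 were higher and 5 lower, also over the list alone (camera, adjusted p = 0.58): the kinase gene Bmx rose 6.33-fold, the gap junction gene Gja5 was 6.20-fold lower and the Notch ligand gene Dll4 2.63-fold lower. Of 9 venous genes 5 were higher and 1 lower (6 and 1 over the list alone), and camera called the list higher (adjusted p = 0.022), though not with an estimated correlation (adjusted p = 0.34). The venous call was also lost without genes of several lists (adjusted p = 0.22) and among genes above the 25th percentile (0.086) or the median (0.15) of levels. Vwf (3.68-fold) and the TIE2 gene Tek (2.89-fold) led this list, and Selp, the P-selectin gene, was 4.12-fold lower. Of 11 lymphatic genes 1, Stab1, was higher and 3 lower, also over the list alone (camera, adjusted p = 0.53), among them Sox18 and the VEGF receptor gene Flt4 (1.77-fold).

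Notch signalling genes fell more often than they rose. Of 17 genes 10 were lower and 2 higher (11 and 2 over the list alone), with a median change of -0.45. Camera called the list lower (adjusted p = 0.0057), though not with an estimated correlation (adjusted p = 0.063). Dll4 and the receptor gene Notch4 were 2.63-fold and 2.61-fold lower, while the ligand gene Jag1 and the target gene Hey2 rose by 0.57 and 0.55. Of 20 genes of VEGF, TIE and BMP receptor signalling 7 were higher and 8 lower, also over the list alone (camera, adjusted p = 0.58). Id3 and Id1, targets of BMP signalling, were 3.97-fold and 3.13-fold lower, and Tek and Nrp1 were 2.89-fold and 2.07-fold higher. Of 21 Wnt signalling genes 5 were higher and 4 lower (6 and 4 adjusted over the list alone). Camera did not call it (adjusted p = 0.31), with a median of 0.08 and an upward direction against a mean of -0.03. Lgr5, a receptor gene for R-spondins, rose 6.93-fold and Fzd6 1.90-fold, and Dkk2, a Wnt antagonist gene, was 7.82-fold lower.

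Inflammatory genes regulated by NF-kB also fell more often than they rose. Of 16 genes 9 were lower and 2 higher, also over the list alone, with a median of -0.28; camera called the list lower (adjusted p = 0.0057), though not with an estimated correlation (adjusted p = 0.063). The chemokine gene Ccl2 fell 6.60-fold, from 11.24 ± 0.06 to 8.52 ± 0.10, and the E-selectin gene Sele fell 4.39-fold, while Vcam1 and Il6 rose 2.95-fold and 1.76-fold. Of 19 genes of blood cell adhesion and the haematopoietic niche 4 were higher and 7 lower, also over the list alone (camera, adjusted p = 0.081). Itga4, whose product binds VCAM1, rose 3.22-fold, and the falls were led by Ccl2 and Cxcl12. Of 21 interferon response genes 5 were higher and 2 lower, also over the list alone (camera, adjusted p = 0.39), with log2 changes of 0.94 for Ifit2, 0.90 for Mx2, -0.75 for Gbp3 and -0.47 for Gbp2. The groups overlapped for Mx2 and Gbp2.

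Cell cycle genes were lower in the Gata4 samples. Of 22 genes 18 were lower and 0 higher (20 and 0 adjusted over the list alone) by limma, with a median change of -0.37. At an unadjusted p under 0.05, 20 were lower and 0 higher, and an exact rank-sum test called 15 lower and 0 higher. Camera called the list lower (adjusted p = 4.9e-10), but not with an estimated correlation (adjusted p = 0.063). Foxm1, a transcription factor gene of dividing cells, was 2.36-fold lower and Rrm2, a ribonucleotide reductase gene, 1.68-fold lower. Of 17 p53 targets 8 were higher and 2 lower, also over the list alone, and camera called the list higher (adjusted p = 0.0061), though not with an estimated correlation (adjusted p = 0.063) or among genes above the median level (adjusted p = 0.056). The sestrin gene Sesn1 rose 5.14-fold and the death receptor gene Fas 2.81-fold, and Plk2 and Gadd45a had log2 changes of -0.66 and -0.37. Of 18 genes of the unfolded protein and amino acid stress responses 10 were lower and 2 higher (11 and 2 over the list alone), called lower by camera (adjusted p = 0.022) but not with an estimated correlation (adjusted p = 0.34). This call was also lost among genes above the 25th percentile (adjusted p = 0.061) or the median (0.14) of levels, and without empty-vector replicates 1 and 2, a pair chosen after seeing the data (0.051). Atf3 was 2.08-fold lower and the chaperone gene Dnajb9 1.47-fold lower, and Sdf2l1 and Sesn2 rose by 0.26 and 0.24. Of 15 cholesterol synthesis genes 5 were lower and 1 higher (7 and 1 over the list alone), called lower by camera (adjusted p = 0.031) but not with an estimated correlation (adjusted p = 0.40). The call of this list was also lost without Gata4 replicate 2 (0.056), Gata4 replicate 3 (0.052) or empty-vector replicate 3 (0.053) and among genes above the 25th percentile (0.084) or the median (0.16) of levels, as adjusted p. Cyp51 and Insig1 were 1.80-fold and 1.66-fold lower, and Lss rose by 0.38. Of 18 glycolysis and hypoxia genes 4 were higher and 6 lower (4 and 7 over the list alone; camera, adjusted p = 0.31). The adrenomedullin gene Adm and the stress gene Ndrg1 were 5.26-fold and 4.50-fold lower, and the glycolytic enzyme genes Pfkfb3 and Hk2 rose 2.38-fold and 1.86-fold.

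Endocytosis and scavenger receptor genes were higher in 11 and lower in 4 of 25 cases, also over the list alone. Camera called the list higher (adjusted p = 0.031), though not with an estimated correlation (adjusted p = 0.31), and the median change (-0.01) was opposite in sign to the mean (0.29). The endocytosis call was also lost without genes of several lists (adjusted p = 0.095), among genes above the 25th percentile (0.061) or the median (0.14) of levels, and without empty-vector replicates 1 and 2, a pair chosen after seeing the data (0.063). The scavenger receptor genes Colec12 and Cd36 rose 5.14-fold and 3.28-fold, and Stab2 and the clathrin light chain gene Cltb were 2.68-fold and 1.35-fold lower. Of 19 mesenchymal transition genes 3 were higher and 7 lower (6 and 9 over the list alone; camera, adjusted p = 0.19). Fn1 and the transcription factor gene Snai1 were 4.60-fold and 2.91-fold lower, and Thbs1, the thrombospondin 1 gene, and Col3a1 rose 3.28-fold and 1.37-fold. Of 23 genes of the heart, where GATA4 is a central factor, 20 did not pass the test (camera, adjusted p = 0.62). Of these 23 genes 14 had a mean level below the median of all genes. Ankrd1 rose 4.36-fold, Tbx20 was 1.82-fold lower, and Mef2c fell by 0.28 with overlapping groups (adjusted p = 0.0497), a call lost in 7 of the 10 fits without 1 sample (adjusted p up to 0.12). The heart list had a median of -0.03 and a downward camera direction against a mean of 0.01. Over the list alone 1 heart gene was higher and 1 lower.

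Camera called 0 of the 5 lists of markers of other cell types. Of 12 hepatocyte markers 0 were called by limma, over all genes or adjusted over the list alone, and 0 also at an unadjusted p under 0.05 and by the exact rank-sum test. All 12 had a mean level below the median of all genes, as had 11 of 13 macrophage and 11 of 12 pericyte markers. Of the 5778 genes with the lowest mean levels 2.08% were called, and of the next 5778 8.34%. With such weak signal, few calls could arise, so the hepatocyte count cannot decide whether these markers changed. Of 13 macrophage and leukocyte markers 1 was higher and 2 lower, also over the list alone: Cd68, a lysosomal protein gene, was 2.33-fold lower, and Cd14 and Adgre1, with group means of at most 3.78, changed by -0.34 and 0.20. The call of Adgre1 was lost in 6 of the 10 fits without 1 sample (adjusted p up to 0.078). Of 12 pericyte and stellate cell markers 1, Rgs5, was higher (0.32), also over the list alone. Of 12 fibroblast markers 4 were higher and 1 lower (5 and 1 over the list alone), with Pi16 and Thy1 up 2.04-fold and 1.47-fold and Pdgfra 2.02-fold lower. Of 12 astrocyte and neuron markers 2 were higher and 1 lower, also over the list alone: the neurofilament gene Nefl rose 3.75-fold to 9.90 ± 0.08, the tubulin gene Tubb3 rose 2.43-fold and the stathmin gene Stmn2 was 2.46-fold lower. The share called, 25% of this list and 23.1% of the macrophage list, was near the 25.6% of all genes. That comparison is not matched for level, as 9 of the 12 astrocyte and neuron markers also lay below the median. Camera's adjusted p was 0.31 for the fibroblast list, 0.58 for the pericyte list and for the astrocyte and neuron list, 0.80 for the macrophage list and 0.89 for the hepatocyte list, while fry called all but the hepatocyte list. Fry makes no comparison with the other genes, so its calls do not set these lists apart.

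**Figure D3:**
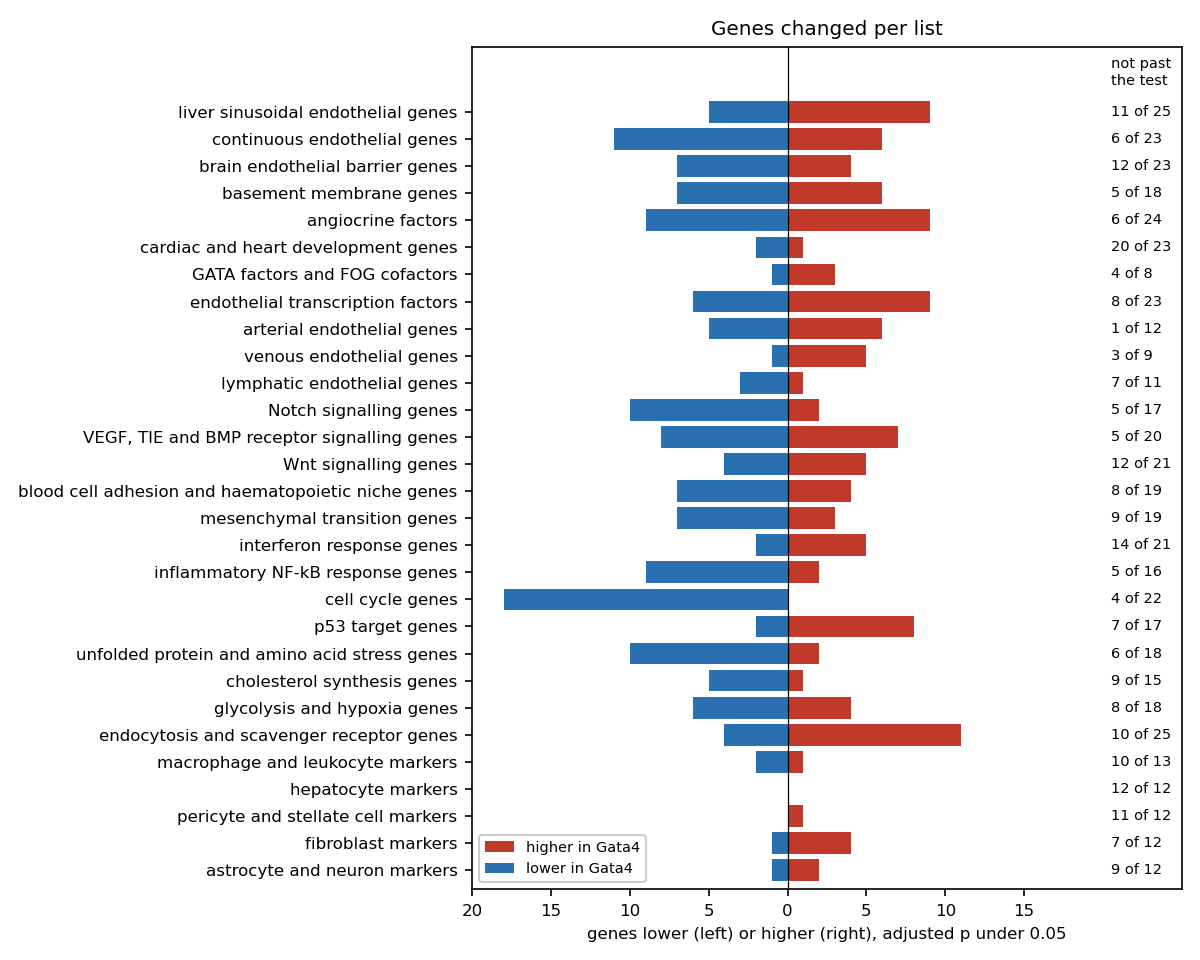
Number of genes lower (blue, left) and higher (red, right) in the Gata4 samples at an adjusted p under 0.05 in each of the 29 preset lists, with the number not past the test at the right. Cell cycle genes were lower in 18 of 22 cases and higher in 0, while most other lists held changes in both directions.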

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

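The test with each gene family counted once, the test without a run of neighbouring genes and the test of other splits of the samples were set down before their results were seen; the other tests in this part, and the adjustment of the family and neighbour tests over 20 chromosomes, were chosen after the result was seen.

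The Gata4 feature rose by 0.34 (log2), less than 1728 other genes that were called higher, although the cells carried a Gata4 vector. Single samples with the other group's label are argued against, since 10 of 10 samples correlated better with their own group than with the other. That the probes do not detect the codon-optimized cDNA remains open: the interval of the change, 0.13 to 0.54, excludes 0, but weak detection of the transgene and a rise of the endogenous gene cannot be told apart without the probe sequences. An exchange of all labels between the groups was not tested.

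Other splits of the 10 samples did not give the count of changed genes. Of 100 of the 126 possible splits into 5 and 5, 1 gave 5915 called genes, and that was the real one; the highest other split gave 0. Each other split mixed samples of both groups, so the group difference entered the spread within its sets and a low count was to be expected. The splits also cannot address a difference between the transduced populations that preceded the sampling. No conclusion on chance is drawn from them.

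When the 20 chromosomes were compared, X-linked genes stood out among the genes at least 2-fold higher: 32 of 361 above the median level (8.86%), against 3.23% of the autosomal genes (Fisher's exact test, two-sided, adjusted p = 1.4e-05 over 20 chromosomes), while 1.94% were at least 2-fold lower, against 2.79%. The Fisher tests here count genes or families as independent units. Their p-values measure no spread between samples and can be too small where genes change together. Extra copies of the whole chromosome that raise most of its genes are argued against by the median change of the X-linked genes, 0.045 with a bootstrap interval of 0.0042 to 0.086, far below the 0.2 set as a bound. A gain that raises only some genes is not addressed by a median. This median was still the highest of the 20 chromosomes, and 115 of the 361 X-linked genes were called higher and 65 lower. The run of Armcx, Gprasp, Bhlhb, Bex and Tceal genes is argued against as the whole cause, since 7.47% of the X-linked genes were at least 2-fold higher without it (Fisher's exact test, p = 0.00012, or 0.0024 adjusted over 20 chromosomes). With each gene family (genes sharing a symbol stem) counted once, the shares were 9.46% and 6.18% (28 of 296 against 307 of 4966, Fisher's exact test, p = 0.036), but the bound set for this test ignored that the X chromosome had been picked among 20, and adjusted for that the excess did not pass (0.060). A family counted if any member rose, and families held 1.22 genes on the X chromosome against 2.25 on the autosomes. Autosomal families thus had more chances to count, so this test cannot decide on shared probes. Among genes with no relative by symbol stem the shares were 7.22% and 2.90% (7 of 97 against 84 of 2893, Fisher's exact test, p = 0.027, or 0.21 adjusted), so probes shared within families stay open, as do the untested hypotheses of an effect of GATA4 and of a difference between the transduced populations that preceded the sampling.

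In 11 of the 236 gene-and-group combinations tested (4.66%; chance flags about 1 in 20), 1 sample stood apart from the other 4, its gap divided by the group's range exceeding 0.71. In the empty-vector group these were Gata2 (0.714, sample 4 low), Ifit2 (0.876, sample 1 low), Il6 (0.740, sample 3 low), Sdf2l1 (0.796, sample 4 low) and Pi16 (0.804, sample 4 low). In the Gata4 group they were Gata5 (0.742, sample 4 high), Pde1a (0.834, sample 3 high), Gpr182 (0.722, sample 2 low), Cd34 (0.742, sample 3 high), Col18a1 (0.722, sample 4 low) and Cyp51 (0.916, sample 5 high). Of the 637 features without a gene symbol, 189 differed between the groups when every feature was tested, 86 higher and 103 lower (29.7%).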

How the results depend on the processing

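The counts of changed genes were stable except against a fold threshold: tested against a 1.5-fold change (limma's treat), 503 genes were higher and 374 lower, a requirement that small changes cannot meet. The exact rank-sum test called 2432 higher and 2433 lower. With 5 samples per group only the 4865 genes whose groups did not overlap passed it, so it repeats that count. Leaving out single samples gave 2621 to 2748 genes higher and 2746 to 2915 lower, and the Gata4 feature kept its call (0.29 to 0.40). With the replicate block, 2721 genes were higher and 2923 lower, 5366 of the main calls were shared, the deviations of same-numbered samples correlated at 0.0040 to 0.13, with 1 of 5 over 0.1, and 2 of the 5 Gata4 samples had their best match among the empty-vector samples in the same-numbered one; the block ended the calls of Mef2c and Adgre1 (adjusted p = 0.11 and 0.054), 2 genes that also lost their call in 7 and 6 of the 10 fits without 1 sample. Without empty-vector replicates 1 and 2, chosen after seeing that their deviations went together (0.21), 2471 genes were higher and 2626 lower, with the calls of Mx2, Adgre1 and Cd14 lost (adjusted p = 0.055, 0.091 and 0.056) and the stress (0.051) and endocytosis (0.063) lists no longer called. No named gene changed its direction past the threshold in any alternative run. Gene list calls depended more on the setting, and values here are adjusted p. With an estimated correlation all 8 called lists lost their call: Notch, NF-kB, cell cycle and p53 (0.063 each), endocytosis (0.31), venous and stress (0.34 each) and cholesterol (0.40). Above the 25th percentile of levels, venous (0.086), stress (0.061), cholesterol (0.084) and endocytosis (0.061) were not called; above the median, venous (0.15), p53 (0.056), stress (0.14), cholesterol (0.16) and endocytosis (0.14) were not. Without genes of several lists, venous (0.22) and endocytosis (0.095) lost their call, while sinusoidal (0.020, higher) and continuous (0.027, lower) gained one; with an intensity trend, blood cell adhesion gained one (0.048). Fry added sinusoidal (0.0055), continuous (0.00011), angiocrine (9.7e-06), GATA (0.0014), arterial (0.0097), lymphatic (5.8e-05), VEGF (0.00011), Wnt (0.00070), blood cell adhesion (3.3e-07), mesenchymal (0.00070), glycolysis (6.3e-06), macrophage (0.010), pericyte (0.017), fibroblast (0.011) and astrocyte (0.0035) lists, and gave the basement membrane list the opposite direction (0.0097, higher). As fry does not compare a list with the other genes, the calls it added do not set those lists apart. Single samples left out moved the cholesterol list between 0.017 and 0.056. Apart from treat, whose threshold shows it, the cause was not tested. Averaging the features of a gene was not run because each gene had 1 feature; camera has no robust option, so the robust trend was run on genes only. Centring on medians changes little, since the arrays had already been quantile-normalized. Of the 5778 genes with the lowest mean levels 2.08% were called, against 51.0% of the 5778 with the highest; whether weak signal or absent expression underlies this was not tested.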

Other observations

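Groups of genes that share a symbol stem were compared after the data had been seen: 662 families of at least 5 genes were tested with camera, and 13 passed at the preset correlation, against 0 with an estimated one (35 at an unadjusted p under 0.05; adjusted p = 0.87 for all but the Man family at 0.92). Homeobox genes of 2 clusters were lower: 5 of 9 Hoxd genes (median -0.82, adjusted p = 0.0069) and 6 of 10 Hoxb genes (-0.47, 0.011), with 0 higher in either. The Hoxd genes that did not pass had group means of at most 3.51 (Hoxd1, empty vector), where values may be background. Among the Hoxb genes that did not pass the means reached 5.31 (Hoxb4, Gata4 samples). The single genes named in this part, apart from Serpinb1a, Tmem255a and Itm2a, were chosen after their values were seen. Hoxd8 fell by 2.27, Hoxb8 by 1.98 and Hoxd9 by 1.60. Among genes with the stems Cdca, Mcm and H2ac (histone genes), 7 of 7, 5 of 9 and 8 of 12 were lower and 0 higher. So were 9 of 19 Nup genes of the nuclear pore and 5 of 5 Smg genes of nonsense-mediated decay.

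Of the X-linked Armcx genes 5 of 6 were higher (median 1.29, adjusted p = 0.00034), as were 4 of 5 lysophosphatidic acid receptor genes (Lpar; 0.76, 0.0094), led by Lpar4 (1.58) and Lpar2 (1.10). With an estimated correlation neither family was called (adjusted p = 0.87 for both). Of 5 isocitrate dehydrogenase genes 4 were higher (median 0.38, adjusted p = 0.021), Idh1 by 1.73 and Idh2 by 0.90, and of 9 genes with the stem Man, which encode mannosidases, 6 were higher and 1 lower (0.35, 0.039). These calls were also lost with an estimated correlation (adjusted p = 0.87 for Idh and 0.92 for Man). In 2 further families camera's direction was upward although most members did not pass the test and the median lay near 0. Of 26 Serpinb protease inhibitor genes 18 did not pass, 7 were higher and 1 was lower (median 0.02, adjusted p = 0.028), with Serpinb1a (5.70) and Serpinb10 (4.20) far above the rest. Of those that did not pass, all but Serpinb1c had group means of at most 3.61, where values may be background. The Serpinb median therefore says little about members expressed in these cells. Of 19 tetraspanin genes (Tspan) 13 did not pass, 6 were higher and 0 lower (median 0.09, adjusted p = 0.024), led by Tspan8 (4.40), Tspan13 (2.39) and Tspan17 (2.14). The Tspan genes that did not pass included some at high levels, such as Tspan31 (11.33 in the empty-vector samples). Neither of these families was called with an estimated correlation (adjusted p = 0.87 for both). The X-linked genes with the largest rises were Tmem255a (6.83), Itm2a (5.13), Gprasp2 (4.25), Pwwp3b (3.51) and Slc9a7 (3.41).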
